A study of Rattus norvegicus with 47 samples.

How the data were processed

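Messenger RNA was sequenced from tissue punches of the striatum and the cerebellum of male and female Sprague-Dawley rats exposed to PCB52 or sham-exposed, per the labels. Per the labels' protocols, punches were lysed in TRIzol, RNA was purified on spin columns, and messenger RNA was enriched by poly(A) capture or by removal of ribosomal RNA, without a statement of which was used for which library. The submitters' processing notes name FastQC, HISAT2 (an aligner) and the rat genome build rn6, with no versions. The read counter, the gene annotation and the use of strand are not given in the sources used here, so reads of a gene could not be told apart from those of an overlapping or antisense gene.

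The deposited tables, 1 per region, hold whole-number counts per gene and library, not normalized, under numeric gene identifiers. Both list 15319 genes. Of these, 15230 identifiers (99.4%) were matched to a symbol in a reference table of the assembly GRCr8, which was used for names only. Group, sex, region and animal number came from the labels. Of 47 samples in the labels, 44 had a column of counts. Cerebellum sham male 5 and striatum sham males 5 and 7 were not analysed here. Libraries are named by region, group and animal number. Within each group the counts of every pair of libraries differed by more than sampling noise (lowest chi-square per degree of freedom 3.49), so no pair was treated as 1 library deposited more than once.

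The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with TMM normalization, the default filter on low counts and robust dispersion. Each region was fitted with 4 group means (sex by treatment), and 12142 genes were tested in striatum and 11690 in cerebellum. Contrasts were PCB52 against sham in males, in females and as the mean of both sexes, the female effect minus the male effect, and females against males within each treatment. A fit of all 44 libraries with 8 group means tested the striatal minus the cerebellar effect in 12446 genes. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. Counts scaled by library size (CPM) are, for a group, the mean ± SD of values scaled by the TMM-adjusted size. CPM of single libraries and of the floor are scaled by library total, and the fold over the floor divides the group mean by it. The log2 fold changes are given with the standard error (SE) of the fit. A list mean is the mean log2 CPM of a list's members, scaled by TMM-adjusted library size with a prior count of 2. The animals are the replicates.

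The 38 gene lists comprised 20 lists of gene functions and 18 of cell type markers. They were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Lists with fewer than 5 measured members were not tested, which left 36 lists in striatum and 33 in cerebellum. The mitochondrially encoded list had 0 measured members of 13 in either region, and the aryl hydrocarbon receptor target list had 4 of 10 in both. In cerebellum the striatal interneuron list had 4 of 10, the ependymal list 3 of 10 and the blood cell list 4 of 13. The preset correlation treats members of a list as nearly independent, so every call within a region was set beside camera with an estimated correlation and fry. Calls of the region comparison were set beside the estimated correlation only, and those with the animal as a block beside neither.

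The lists, tests, contrasts, named-gene rule and first set of alternatives were chosen before the data were examined. For each PCB52 comparison the rule took up to 12 genes per direction past the threshold with a mean of at least 1 CPM and a symbol that was not a provisional locus name. Where fewer than 10 passed, it took the genes of lowest p up to 10 in all. Interactions and sex comparisons took 6 by the same rule. Each list called in a PCB52 comparison added its 2 members of lowest p. Some rule genes were left out of the text, mostly for an uncertain function, and 4 genes are not reported here. Other members named for a list were chosen after their values were seen.

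Results were also computed with DESeq2 1.42.0, RLE size factors, no filter on low counts, only the libraries of the groups compared, limma voom with sample quality weights, surrogate variables from svaseq (sva 3.50.0), leaving out each library in turn, the animal as a block in the region comparison, and other list tests. Further alternatives were chosen after seeing the data. They left out libraries with Xist and Eif2s3y both above 3 CPM, libraries with a list of another tissue more than 2 log2 units above the region's median, or libraries with a ribosomal protein list mean above 9.2, or added that mean as a covariate. The olfactory bulb and forebrain neuron panels behind the second of these were also chosen after seeing the data, partly from genes high in these libraries. The lists checked for another tissue were choroid plexus, cerebellar granule cell and olfactory bulb in striatum, and choroid plexus and forebrain neuron in cerebellum. Striatal libraries high in cortical or thalamic genes were not left out for those genes.

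The same number marks the same animal in both regions, per the labels, and 21 animals had libraries of both. Over 11408 genes the median correlation of deviations from the group means was 0.0961 between regions of the same animal and 0.00450 between different animals. It was over 0.1 in 10 of 21 pairs, and 3 animals correlated best with their own number. The block by animal was fitted only where regions were compared, since no other comparison holds an animal more than once.

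The fits were tested on simulated counts drawn from the real means and library sizes. At a simulated fold of 2, 86.6% of changed genes were recovered in striatum males, 86.6% in striatum females, 58.2% in cerebellum males and 77.6% in cerebellum females, each of 67 changed genes among 12075 in striatum and 11630 in cerebellum. At a fold of 1.5 the shares were 34.3%, 53.7%, 23.9% and 46.3%. For the mean of both sexes at a fold of 2, 91.0% were recovered in either region, and for the region comparison 74.5% of 200 among 12294. Simulated genes varied independently of each other, which the real genes did not. Total counts per library ran from 5684508 to 15865054, so a gene at 1 CPM rested on few counts in the shallowest libraries.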

Results

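Rats inhaled PCB52, a polychlorinated biphenyl with 4 chlorine atoms, through the nose for 4 h a day over 28 days, with exposure assigned at 39 days of age in males and 42 in females. Gene expression in striatum and cerebellum was compared between exposed and sham animals of each sex. Striatum gave 4 libraries of sham males, 6 of PCB52 males, 6 of sham females and 6 of PCB52 females, and cerebellum gave 5, 5, 6 and 6. Total counts in striatum ran from 6312087 to 8914523 in sham males, 6271704 to 6750644 in PCB52 males, 6334372 to 7004714 in sham females and 5684508 to 6944007 in PCB52 females. In cerebellum they ran from 6731768 to 8442982, 6766637 to 10436049, 6910329 to 7607827 and 6524400 to 15865054 in the same order.

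Striatum of females and males differed in genes of the sex chromosomes. Eif2s3y (gene 100312984), which encodes a subunit of a translation initiation factor from the Y chromosome, stood at 44.5 ± 7.45 CPM (SD, n = 4) in sham males and 45.2 ± 4.45 CPM (SD, n = 6) in PCB52 males, and had 0 counts in each of 12 female libraries. With a floor of 3 counts over those 12 libraries, 0.0382 CPM, it was at least 1167-fold higher in sham males and at least 1184-fold higher in PCB52 males. Ddx3y, a Y-linked RNA helicase gene, was at least 1109-fold and 1215-fold higher in males by the same floor. Eif2s3, the X-linked counterpart of Eif2s3y, was higher in females by 0.63 ± 0.09 on the log2 scale (SE) in sham animals and 0.58 ± 0.08 in PCB52 animals (edgeR adjusted p = 0.00147 and 4.68e-04). In sham animals this call was lost when only the libraries compared were fitted (edgeR adjusted p = 0.327). Xist, the RNA that silences an X chromosome, stood at 676 ± 171 CPM (SD, n = 6) in PCB52 females and 0.708 ± 0.469 in PCB52 males (n = 6; edgeR adjusted p = 2.10e-04). In sham animals it stood at 525 ± 219 and 34.8 ± 68.1 CPM and did not pass in edgeR, but it did with limma (limma adjusted p = 0.00103). Sham male 3 held 135 CPM of Xist beside 33.4 CPM of Eif2s3y, and no other striatal male library exceeded 1.63 CPM of Xist. In all, edgeR called 4 genes in sham animals, 2 higher and 2 lower in females, and 5 in PCB52 animals, 3 higher and 2 lower. The remaining call in each was id680227, a gene with no matched symbol that was higher in females. In sham animals it was also not called with only the libraries compared.

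**Figure D1:**
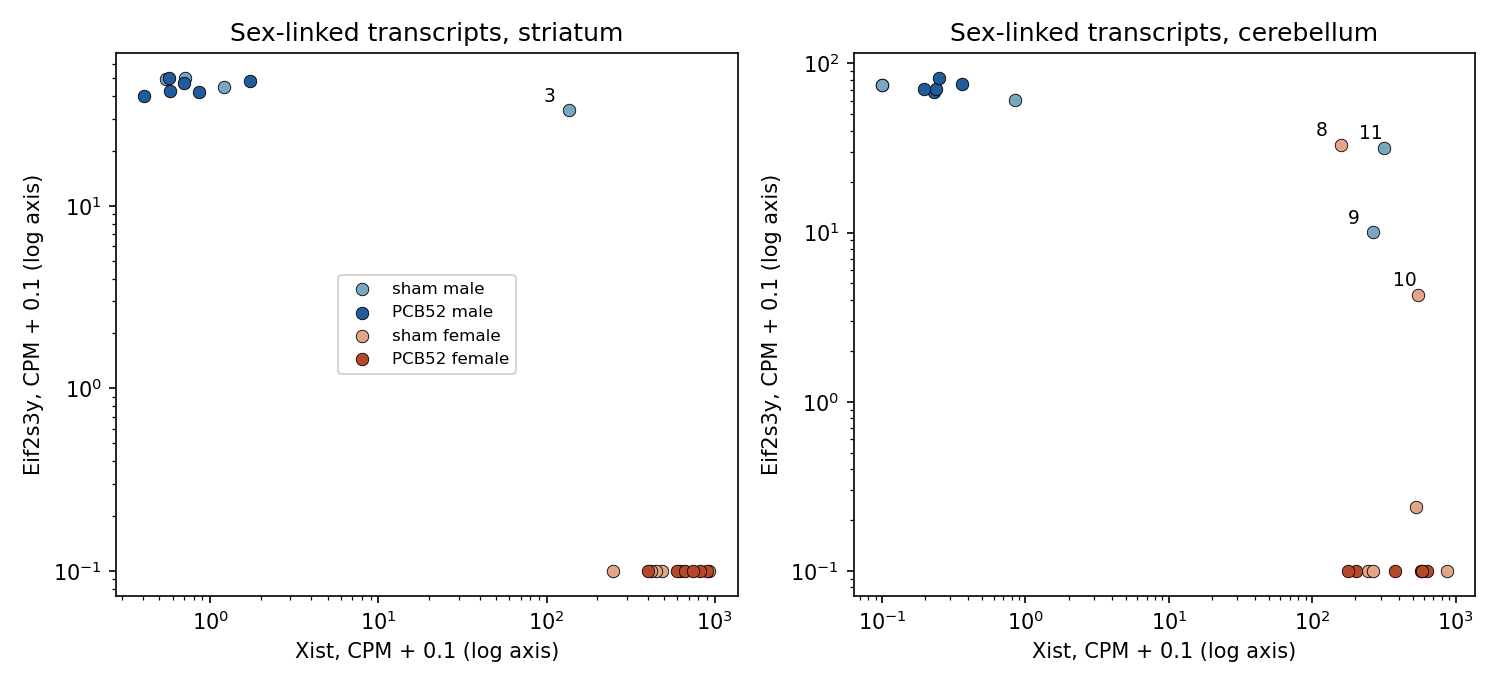
Xist against Eif2s3y in CPM plus 0.1, both on log axes, with 1 point per library coloured by group, striatum left and cerebellum right. Numbered points are the libraries with both transcripts above 3 CPM: sham male 3 in striatum and sham libraries 8, 9, 10 and 11 in cerebellum.

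In cerebellum, transcripts of both sexes occurred together in 4 sham libraries. Females 8 and 10 held 32.9 and 4.20 CPM of Eif2s3y, while the other 10 female libraries held at most 0.139 CPM. Males 9 and 11 held 265 and 314 CPM of Xist, while the other 8 male libraries held at most 0.743 CPM. In PCB52 cerebellum Xist was 11.27 ± 1.91 higher and Eif2s3y 12.27 ± 1.97 lower in females (log2, SE), with an edgeR adjusted p of 0.0758 for each. The size of both folds depends on how the fit handles very low counts. PCB52 females held at most 0.139 CPM of Eif2s3y, and PCB52 males at most 0.743 CPM of Xist. edgeR called 0 genes between the sexes in sham and 0 in PCB52 cerebellum, with 123 and 379 genes at an unadjusted p under 0.05, DESeq2 called 0 and 9, and limma called 0 and 2. Without the 4 cerebellar libraries, edgeR called 4 genes in sham animals (Eif2s3y, Xist, Ddx3y and Eif2s3) and 5 in PCB52 animals.

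Sham females stood above sham males in the glucocorticoid-responsive list, genes induced by corticosterone through its receptor. In striatum 14 of 17 members were higher, with a median log2 difference of 0.31 (camera adjusted p = 4.48e-05), and in cerebellum 15 of 16, with a median of 0.35 (camera adjusted p = 9.77e-08). The adjusted p was 0.619 and 0.120 with an estimated correlation. Sexes are those of the labels, and 4 of the 11 sham cerebellar libraries held transcripts of both sexes. In cerebellum the list mean was 0.28 higher in females with all libraries and 0.47 higher without these 4, which leaves 3 males and 4 females. The oligodendrocyte list, myelin genes such as Ugt8 and Mag, was lower in sham females in striatum (12 of 12 members, median -0.22, camera adjusted p = 8.87e-05) and higher in cerebellum (12 of 12, median 0.42, camera adjusted p = 2.86e-09). With an estimated correlation these gave an adjusted p of 0.619 and 0.360. The cerebellar difference of its list mean was 0.39 with all libraries and 0.53 without the 4. Microglial genes were higher in sham female cerebellum in 12 of 12 members (median 0.24, camera adjusted p = 6.08e-07; adjusted p = 0.153 with an estimated correlation), with a list mean difference of 0.32, and 0.47 without the 4. The choroid plexus list was lower in 7 of 7 (median -1.32, camera adjusted p = 7.22e-05; adjusted p = 0.360 with an estimated correlation). Sham male 1 had a list mean of 6.04, and every other cerebellar library was at or below 2.73. In PCB52 striatum, the striatal projection neuron list was lower in females in 12 of 12 members (median -0.22, camera adjusted p = 1.03e-05; adjusted p = 0.638 with an estimated correlation). PCB52 females 14 and 24 had list means of 8.66 and 8.47, the other 4 PCB52 females 9.32 to 9.48 and PCB52 males 9.21 to 9.53. The circadian clock list was lower in 12 of 16 (median -0.08, camera adjusted p = 0.00626; adjusted p = 0.638 with an estimated correlation), and its camera adjusted p was 0.121 without PCB52 female 24. In PCB52 cerebellum, interferon response genes were lower in females in 16 of 21 members (median -0.41, camera adjusted p = 0.0110; adjusted p = 0.632 with an estimated correlation). Over both regions and treatments camera called 7, 9, 10 and 8 lists between the sexes (striatum sham, striatum PCB52, cerebellum sham, cerebellum PCB52), and 0 of them with an estimated correlation.

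In striatum of males, PCB52 and sham libraries differed little. Xist was 5.56 ± 1.25 lower in PCB52 males on the log2 scale (SE), a difference carried by sham male 3, without which it was 0.052. P2rx4, an ATP-gated ion channel gene, stood at 16.1 ± 2.43 CPM in PCB52 males (SD, n = 6) and 24.1 ± 3.59 in sham males (SD, n = 4). Cdca7l and Gpr37l1, a receptor gene of glia, had log2 fold changes of -0.78 ± 0.27 and -0.29 ± 0.10 (SE). The ATP synthesis, ribosomal, xenobiotic and stress lists were not called. Genes of cortical excitatory neurons were higher in 9 of 9 measured members, with a median log2 fold change of 1.09 (camera adjusted p = 0.0428; adjusted p = 0.989 with an estimated correlation). Among them, Slc17a7, which loads glutamate into vesicles, stood at 89.1 ± 131 CPM against 13.1 ± 7.44, and Tbr1, a cortical transcription factor gene, had a log2 fold change of 2.56 ± 1.23. PCB52 male 19 alone held 348 CPM of Slc17a7, and the list's adjusted p was 0.529 without it, 0.112 without PCB52 male 23, 0.185 without sham male 3 and 0.0885 without sham male 1. edgeR called 0 genes (smallest adjusted p = 1.00), with 109 genes at an unadjusted p under 0.05. Independent genes without an effect would give about 607. DESeq2 called 1 (Xist) and limma 0.

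In striatum of females, PCB52 libraries held less of the transcripts that glucocorticoids induce. The mean of the glucocorticoid-responsive list was 5.03 in sham females, 4.69 in PCB52 females, 4.73 in sham males and 4.77 in PCB52 males. Sham females were thus the highest group, and they also enter the comparison of the sexes in sham animals and the interaction. The list was lower in 14 of 17 members, with a median log2 fold change of -0.36 (camera adjusted p = 8.22e-06; adjusted p = 0.832 with an estimated correlation), and 6 members fell when adjusted over the list alone, against 0 over all genes tested. Tsc22d3 (gene 83514), a glucocorticoid-induced leucine zipper gene, stood at 95.7 ± 12.3 CPM in PCB52 females and 136 ± 25.3 in sham females (SD, n = 6 each), a log2 fold change of -0.51 ± 0.12 (SE). Mt2A, a metallothionein gene that binds zinc, had a change of -1.06 ± 0.30. The others were Klf9 (-0.41), Ddit4 (-0.47), Angptl4 (-0.36) and Fkbp5 (-0.26), a co-chaperone of the glucocorticoid receptor. Mt2A and Mt1 (-0.84 ± 0.25) were also the 2 members of the NRF2 antioxidant list that fell over the list alone, while that list as a whole was lower in 19 of 26 members (median -0.14, camera adjusted p = 0.0217; adjusted p = 0.832 with an estimated correlation).

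Nuclear-encoded genes of oxidative phosphorylation were lower in PCB52 female striatum in 38 of 38 members (median log2 fold change -0.26, camera adjusted p = 6.01e-11) and cytosolic ribosomal protein genes in 39 of 39 (median -0.31, camera adjusted p = 1.48e-11). With an estimated correlation the adjusted p was 0.832 for both. Uqcrc2, a subunit of respiratory complex III, had a change of -0.21 ± 0.08, and Rplp2, a protein of the ribosomal stalk, -0.39 ± 0.15. Sham female 12 had the highest ribosomal list mean in striatum, 9.34. Without it the difference of the ribosomal list mean went from -0.30 to -0.15 and that of oxidative phosphorylation from -0.25 to -0.14. Dopamine signalling genes were lower in 22 of 25 members (median -0.21, camera adjusted p = 0.00196) and projection neuron markers in 11 of 12 (median -0.23, camera adjusted p = 0.0211), each with an adjusted p of 0.832 with an estimated correlation. Drd1, a dopamine receptor gene, stood at 310 ± 85.6 against 379 ± 50.4 CPM (SD, n = 6 each). PCB52 females 14 and 24 carried this: they held 224 and 202 CPM of Drd1, and the other 4 PCB52 females 323 to 387. Their projection neuron list means were 8.66 and 8.47 against 9.32 to 9.48. They also held 347.4 and 370.6 CPM of Slc17a7, a gene of cortical neurons, and the highest thalamic, septal or hypothalamic list means in striatum, 3.81 and 4.12. Without female 14 the camera adjusted p was 0.0379 for dopamine signalling and 0.175 for projection neurons, and without female 24 it was 0.121 and 0.442. Glutamatergic synapse genes were higher in 27 of 35 (median 0.13, camera adjusted p = 0.0269; adjusted p = 0.832 with an estimated correlation), among them Shank1, a postsynaptic scaffold gene (0.92 ± 0.34), and Grin2c, an NMDA receptor subunit gene (0.33 ± 0.11). The camera adjusted p of that list was 0.129 without PCB52 female 14 and 0.235 without sham female 12. Th, which makes the dopamine precursor, had a log2 fold change of -2.20 ± 0.84 and of 0.33 without sham female 12, the library with an olfactory bulb panel mean of 5.76.

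Choroid plexus genes were higher in PCB52 female striatum in 9 of 9 members, and all 9 rose when adjusted over the list alone. Ttr, a thyroid hormone carrier made by that tissue, stood at 1768 ± 4272 CPM against 20.8 ± 17.7 (SD, n = 6 each). The list had a median log2 fold change of 3.33 (camera adjusted p = 0.0205; adjusted p = 0.832 with an estimated correlation). PCB52 female 20 carried it: its list mean was 7.65 against at most 2.01 in the other females of the group, and without it the list's adjusted p was 0.407. Among the genes of lowest p were Tbc1d2, a regulator of vesicle traffic (0.77 ± 0.17), Zfp189, a zinc finger gene (-0.79 ± 0.17), Cercam (0.80 ± 0.17), Ppp1r2, an inhibitor of protein phosphatase 1 (-0.37 ± 0.08), Itga7, a laminin receptor subunit (0.61 ± 0.14), Fzd7, a Wnt receptor (1.28 ± 0.29), and P3h2, a collagen-modifying enzyme (1.31 ± 0.30). For all of these the edgeR adjusted p was 0.222. Itga7 is also on the thyroid hormone-responsive list, which was not called. edgeR called 0 genes, with 1633 at an unadjusted p under 0.05. Independent genes without an effect would give about 607, but 25 of 100 relabellings of the samples, the real one included, gave as many as 1633. DESeq2 called 23, 19 higher and 4 lower, including each gene named in the sentence on the lowest p and Tsc22d3 (DESeq2 adjusted p = 0.0406), and limma called 0.

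Averaged over both sexes, PCB52 striatum was lower in the same kinds of genes by smaller amounts. Oxidative phosphorylation was lower in 38 of 38 members (median -0.14, camera adjusted p = 4.34e-08), and ribosomal proteins in 39 of 39 (median -0.15, camera adjusted p = 9.48e-08). With an estimated correlation the adjusted p was 0.821 for both. The females made this difference, since ribosomal list means were 8.53 in PCB52 and 8.52 in sham males, and those of oxidative phosphorylation 7.45 and 7.46. Without sham female 12 the averaged difference of list means went from -0.14 to -0.072 for ribosomal proteins and from -0.13 to -0.074 for oxidative phosphorylation. Also lower were dopamine signalling genes in 21 of 25 (median -0.10, camera adjusted p = 0.01004), NRF2 genes in 20 of 26 (median -0.07, camera adjusted p = 0.0418) and glucocorticoid-responsive genes in 14 of 17 (median -0.16, camera adjusted p = 9.73e-04). Glutamatergic synapse genes were higher in 29 of 35 (median 0.10, camera adjusted p = 0.00417). These 4 lists also had an adjusted p of 0.821 with an estimated correlation. Without PCB52 female 14 or 24 the camera adjusted p of dopamine signalling was 0.0705 or 0.194. Tsc22d3 fell when adjusted over its list alone (-0.33 ± 0.09). Lime1, a signalling adaptor gene (0.32 ± 0.07), Fcho1, which acts in endocytosis (0.33 ± 0.08), Tbkbp1 (0.35 ± 0.09) and Slc9a4, a sodium-proton exchanger gene (1.10 ± 0.31), were among the genes of lowest p (edgeR adjusted p = 0.774). edgeR called 0 genes with 704 at an unadjusted p under 0.05, and DESeq2 and limma called 0.

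The female minus the male effect in striatum was negative for the glucocorticoid-responsive list in 16 of 17 members (median -0.39, camera adjusted p = 3.56e-05; adjusted p = 0.712 with an estimated correlation), with Fkbp5 at -0.42 ± 0.15 and Klf9, a transcription factor gene, at -0.48 ± 0.21. It was also negative for ribosomal proteins (39 of 39, median -0.33, camera adjusted p = 8.26e-10), oxidative phosphorylation (38 of 38, median -0.24, camera adjusted p = 6.39e-08) and dopamine signalling (21 of 25, median -0.20, camera adjusted p = 0.0119), each again with 0.712 with an estimated correlation. Without sham female 12 the difference of effects on the list mean went from -0.31 to -0.17 for ribosomal proteins and from -0.24 to -0.13 for oxidative phosphorylation. Without PCB52 female 14 or 24 the camera adjusted p of dopamine signalling was 0.116 or 0.261. It was positive for choroid plexus (9 of 9, median 3.93, camera adjusted p = 0.00657), meningeal fibroblast (11 of 12, median 0.74, camera adjusted p = 0.0308) and thalamic, septal or hypothalamic neuron genes (5 of 7, median 0.37, camera adjusted p = 0.0292). These 3 lists also had an adjusted p of 0.712 with an estimated correlation. The first 2 had their highest value in PCB52 female 20 and the third in PCB52 females 24 and 14. Without female 14 or 24 the camera adjusted p of the third was 0.0598 or 0.0744. Single genes of lowest p were Trip10 (0.85 ± 0.19), Xist (5.92 ± 1.47, and 0.31 without sham male 3), Zfp39 (-0.84 ± 0.21), Fxyd7, a regulator of the sodium pump (-0.92 ± 0.24), and Erbb2, a growth factor receptor gene (0.98 ± 0.27), with a smallest edgeR adjusted p of 0.914. edgeR called 0 genes with 471 at an unadjusted p under 0.05, and DESeq2 and limma called 0.

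In cerebellum of males, 3 transcription factor genes induced by neuronal activity had the lowest p among immediate early genes. Of the 5 sham males, 9 and 11 held transcripts of both sexes. Their female shares by Xist were 0.594 and 0.706, and their male shares by Eif2s3y and Ddx3y 0.0857 and 0.470. The results of this comparison include them and need not be of males alone. Nr4a3 (gene 58853), an orphan nuclear receptor gene, stood at 1.69 ± 0.808 CPM in PCB52 males and 6.18 ± 1.89 in sham males (SD, n = 5 each), a log2 fold change of -1.84 ± 0.48 (SE). Nr4a2, its relative, had a change of -1.10 ± 0.29, and Fosb, a subunit of AP-1, -1.82. These 3 genes fell when adjusted over the immediate early list alone and 0 over all genes tested. Fosb had a mean of 1.37 CPM over the cerebellar libraries, so its change rests on few counts. The list as a whole was not called (14 of 21 members lower, median -0.14, camera adjusted p = 0.0958). Ribosomal protein genes were higher in 39 of 39 members (median 0.75, camera adjusted p = 7.85e-11) and oxidative phosphorylation genes in 37 of 38 (median 0.55, camera adjusted p = 2.99e-07). With an estimated correlation the adjusted p was 0.793 for both. Rps4x stood at 437 ± 224 against 246 ± 70.4 CPM (SD, n = 5 each), and Ndufs3, a complex I subunit gene, had a change of 0.56 ± 0.24.

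Synaptic genes moved the other way in male cerebellum, with sham males 9 and 11 again included. Glutamatergic synapse genes were lower in 30 of 35 members (median -0.36, camera adjusted p = 3.62e-04; adjusted p = 0.793 with an estimated correlation), among them Grin2b, an NMDA receptor subunit gene (-1.27 ± 0.39). GABAergic synapse genes were lower in 20 of 22 (median -0.35, camera adjusted p = 3.62e-04; adjusted p = 0.793 with an estimated correlation), among them Abat, which breaks down GABA (-0.42 ± 0.17). Calcium handling genes were lower in 29 of 37 (median -0.47, camera adjusted p = 0.00186), among them Itpr1, the calcium channel of Purkinje cell stores (-0.54 ± 0.25), and cerebellar interneuron markers in 7 of 7 (median -0.48, camera adjusted p = 0.0311). Both had an adjusted p of 0.793 with an estimated correlation. The ribosomal list mean of PCB52 males 15 and 23 was 9.59 and 10.1, above the highest sham cerebellar library, 9.01. Other genes of lowest p were Xist (-9.39 ± 1.89, sham males 9 and 11), Ttr (-6.31 ± 1.66, sham male 1), Snhg4, a non-coding host gene of small nucleolar RNAs (1.29 ± 0.29), Msx3, a homeobox gene (1.21 ± 0.31), and Cdk14 (-0.41 ± 0.11). For all of them the edgeR adjusted p was 0.313. edgeR called 0 genes, DESeq2 called 1 (Xist) and limma 0. In edgeR 1673 genes had an unadjusted p under 0.05, where independent genes without an effect would give about 584. Of 100 relabellings of the samples, the real one included, 16 gave as many as 1673.

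**Figure D2:**
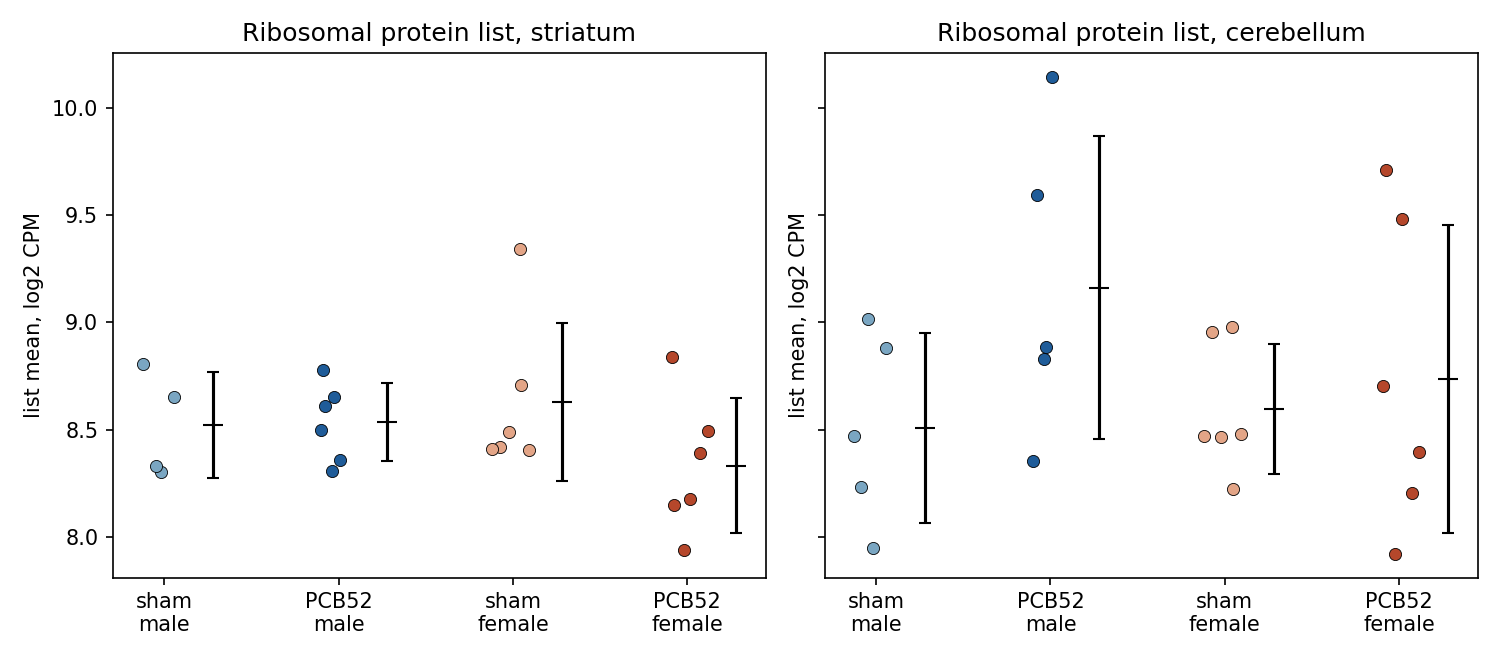
Mean log2 CPM of the cytosolic ribosomal protein list per library in the 4 groups, striatum left and cerebellum right, with the group mean and SD as bars beside the points. In cerebellum 4 of 11 PCB52 libraries lie above the highest of 11 sham libraries at 9.01, and in striatum 0 of 12 lie above the highest sham library at 9.34.

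In cerebellum of females, the glucocorticoid-responsive list was lower after PCB52 in 15 of 16 members, with a median log2 fold change of -0.27 (camera adjusted p = 5.43e-10), and it was the only list of any comparison called with an estimated correlation (adjusted p = 0.0425 with an estimated correlation). fry gave an adjusted p of 0.106. The list mean was 4.77 in sham females, 4.34 in PCB52 females, 4.48 in sham males and 4.46 in PCB52 males. Sham females were thus the highest group. They also enter the comparison of the sexes in sham animals and the interaction, so those results are not independent of this one. Without sham females 8 and 10, which held transcripts of both sexes, the difference of list means went from -0.43 to -0.48. Pdk4, a kinase that restrains glucose oxidation, stood at 2.79 ± 0.742 CPM against 5.17 ± 2.85 in sham females (SD, n = 6 each), a log2 fold change of -0.86 ± 0.30. Sgk1, a glucocorticoid-induced kinase gene, stood at 57.3 ± 19.5 against 85.5 ± 32.4 CPM (-0.58 ± 0.22). 0 members passed when adjusted over the list alone. The call held in each alternative of camera that was run, with a camera adjusted p of at most 8.14e-06 when any 1 library was left out. Those fits kept the preset correlation, so they do not bear on correlation between the members. The estimated correlation was not run with a library left out. Its 0.0425 was adjusted over the lists of this comparison and not over the comparisons.

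**Figure D3:**
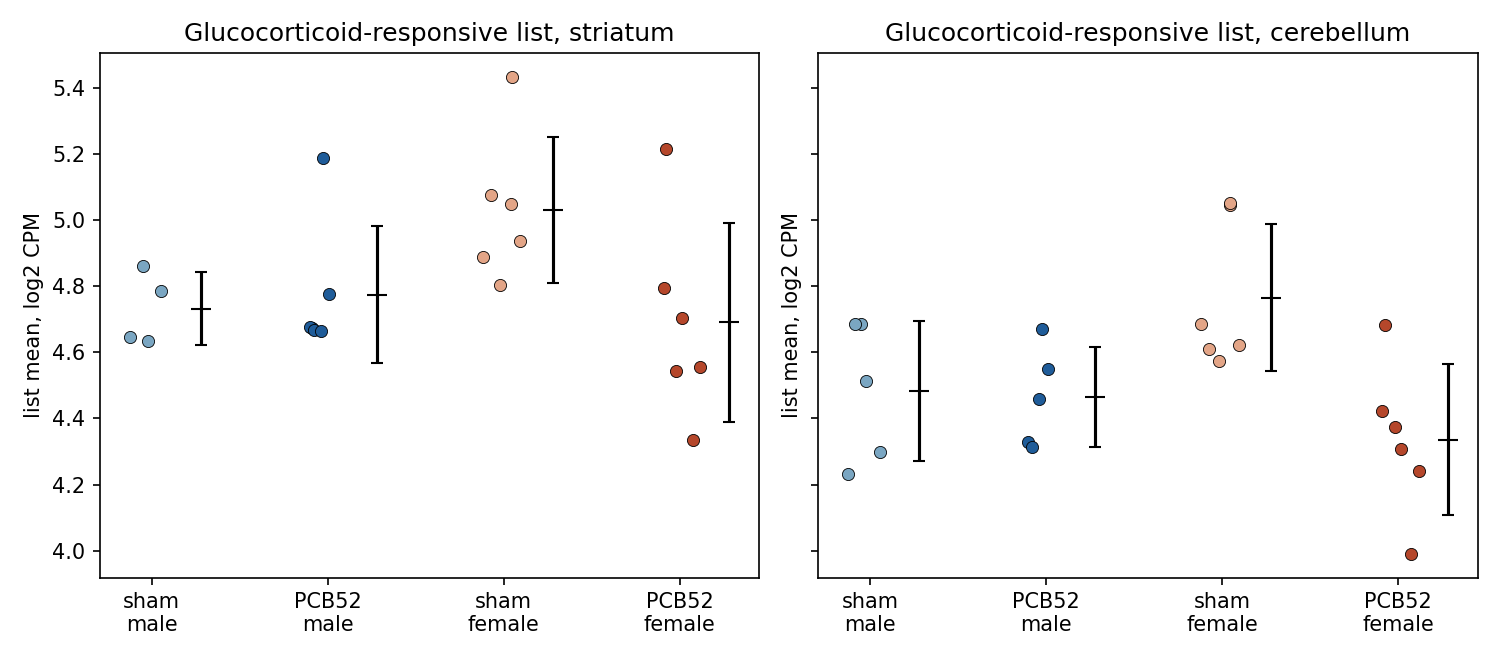
Mean log2 CPM of the glucocorticoid-responsive list per library in the 4 groups, striatum left and cerebellum right, with the group mean and SD as bars beside the points. In cerebellum PCB52 females lie at 4.34 ± 0.227 and sham females at 4.77 ± 0.223 (n = 6 each).

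Myelin genes were lower in PCB52 female cerebellum in 12 of 12 members (median -0.48, camera adjusted p = 4.84e-10; adjusted p = 0.241 with an estimated correlation). The oligodendrocyte list mean was 8.04 in sham females, 7.56 in PCB52 females, 7.65 in sham males and 7.84 in PCB52 males. Sham females were again the highest group, shared with the comparison of the sexes in sham animals and the interaction. Ugt8, which makes myelin galactolipids, stood at 66.8 ± 21.7 against 114 ± 36.2 CPM and Mag, a myelin glycoprotein gene, at 145 ± 43.0 against 217 ± 62.5 (SD, n = 6 each). Oligodendrocyte precursor genes were lower in 8 of 10 (median -0.26, camera adjusted p = 4.00e-04; adjusted p = 0.2004 with an estimated correlation), among them Enpp6 (-0.64 ± 0.26). Immediate early genes were lower in 14 of 21 (median -0.20, camera adjusted p = 2.36e-04; adjusted p = 0.287 with an estimated correlation), with Nr4a2 at -0.77 ± 0.26 and Nr4a1 at -0.73 ± 0.26. Without PCB52 female 14 the adjusted p of that list was 0.0702. Cholesterol synthesis genes were lower in 16 of 21 (median -0.05, camera adjusted p = 0.0104; adjusted p = 0.287 with an estimated correlation), with Sqle, squalene epoxidase, at -0.27 ± 0.09. Microglial genes were lower in 9 of 12 (median -0.07, camera adjusted p = 0.0151; adjusted p = 0.398 with an estimated correlation), with Csf1r, the receptor that sustains microglia, at -0.33 ± 0.11. Inflammatory and NF-kappaB target genes were lower in 10 of 12 (median -0.18, camera adjusted p = 0.0155; adjusted p = 0.201 with an estimated correlation). Astrocyte genes were lower in 8 of 10 (median -0.13, camera adjusted p = 0.0487; adjusted p = 0.249 with an estimated correlation). Meningeal fibroblast genes were lower in 11 of 12 (median -0.23, camera adjusted p = 0.0487; adjusted p = 0.822 with an estimated correlation).

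Ribosomal protein genes were higher in PCB52 female cerebellum in 39 of 39 members (median 0.27, camera adjusted p = 0.0113) and oxidative phosphorylation genes in 34 of 38 (median 0.19, camera adjusted p = 0.0487), each with an adjusted p of 0.822 with an estimated correlation. PCB52 females 16 and 20 had the highest ribosomal list means of the females, 9.48 and 9.71. Without either the ribosomal list was not called (camera adjusted p = 0.898 and 0.492), and without female 20 its direction turned. Oxidative phosphorylation was also not called without either of these females, and its direction turned in both cases. The sex chromosome list was lower in 7 of 7 members (median -0.13, camera adjusted p = 0.0487; adjusted p = 0.249 with an estimated correlation). Eif2s3y and Ddx3y fell over the list alone, and Eif2s3y stood at 6.07 ± 12.9 CPM in sham females (SD, n = 6), where females 8 and 10 held it.

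The genes of lowest p in female cerebellum were neuronal transcripts that are abundant in the forebrain. Ddn, a dendrite protein gene (5.68 ± 1.23), Cck, a neuropeptide gene (5.35 ± 1.20), Nrgn, a postsynaptic calmodulin-binding protein gene (3.98 ± 0.95), Camkv (3.02 ± 0.71) and Ctxn1 (2.16 ± 0.52) were high in PCB52 females 16, 18 and 24. The forebrain panel means of these libraries were 5.78, 5.33 and 6.93 against at most 2.71 in the other cerebellar libraries. This panel was chosen partly from genes high in these libraries. Of the cortical excitatory list, chosen beforehand, 4 of 27 values in the 3 libraries exceeded 2 times the cerebellar median, and 0 of 9 in female 16. Members such as Slc17a7 were already high in cerebellum (median 1017 CPM), so a small admixture could not double them. Sdc2, a heparan sulfate proteoglycan gene, stood at 61.5 ± 5.57 against 77.8 ± 8.32 CPM and Neurl1, a ubiquitin ligase gene, at 90.4 ± 5.11 against 75.0 ± 5.32 (SD, n = 6 each). edgeR called 0 genes (smallest adjusted p = 0.926) with 369 at an unadjusted p under 0.05 and limma called 0. DESeq2 called 9, including Ddn, Cck, Camkv, Nrgn, Ctxn1 and Neurl1.

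Averaged over both sexes, immediate early genes were lower in PCB52 cerebellum. Of 21 measured members 7 fell and 2 rose when adjusted over the list alone. Those that fell were Fosb (-1.51, at a mean of 1.37 CPM), Nr4a3 (-1.33 ± 0.31), Npas4, an activity-dependent transcription factor gene (-1.03), Nr4a2 (-0.93 ± 0.19), Fos (-0.89), Nr4a1 (-0.70) and Fosl2 (-0.52), and those that rose were Ier5 (0.25) and Arc, a synaptic plasticity gene (0.23). The list was lower in 13 of 21 members with a median of -0.24 (camera adjusted p = 0.00715; adjusted p = 0.732 with an estimated correlation). Its adjusted p was 0.149 without the libraries holding both sexes' transcripts and 0.0513, 0.0851 and 0.0800 without sham male 9, PCB52 male 13 and PCB52 female 14. Nr4a2 (gene 54278) stood at 7.62 ± 2.54 against 16.4 ± 3.58 CPM in males (SD, n = 5 each) and 11.1 ± 4.54 against 18.8 ± 5.00 in females (SD, n = 6 each). Its edgeR adjusted p was 0.326, that of DESeq2 0.00452 and that with surrogate variables in edgeR 0.0487.

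Ribosomal protein (39 of 39 higher, median 0.52, camera adjusted p = 1.62e-09) and oxidative phosphorylation genes (36 of 38 higher, median 0.37, camera adjusted p = 2.75e-06) were higher, with an adjusted p of 0.732 for both with an estimated correlation. GABAergic synapse (19 of 22 lower, median -0.15, camera adjusted p = 0.00373), glutamatergic synapse (28 of 35 lower, median -0.20, camera adjusted p = 0.00692) and calcium handling genes (27 of 37 lower, median -0.21, camera adjusted p = 0.0273) were lower, as were sex chromosome genes (7 of 7, median -0.30, camera adjusted p = 0.0339). Each of these also had an adjusted p of 0.732 with an estimated correlation. Rtn4r, a receptor for myelin inhibitors (0.30 ± 0.07), Neurl1 (0.22 ± 0.05), Sdc2 (-0.27 ± 0.06), Dpf1 (0.32 ± 0.07), Dus3l (0.22 ± 0.05), Hnrnph2, a splicing factor gene (-0.24 ± 0.06), and Cavin2, which shapes caveolae (-0.61 ± 0.14), were also among the genes of lowest p. edgeR called 0 genes, DESeq2 called 21, 11 higher and 10 lower, limma called 0, and edgeR with surrogate variables called 60, 31 higher and 29 lower. In the main edgeR fit 1727 genes had an unadjusted p under 0.05, where independent genes without an effect would give about 584. Of 100 relabellings of the samples, the real one included, 8 gave as many as 1727.

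The female minus the male effect in cerebellum was negative for oligodendrocyte genes in 12 of 12 members (median -0.70, camera adjusted p = 1.42e-07; adjusted p = 0.580 with an estimated correlation), with Mag at -0.71 ± 0.37. It was negative for microglial genes in 12 of 12 (median -0.36, camera adjusted p = 0.00160), glucocorticoid-responsive genes in 15 of 16 (median -0.38, camera adjusted p = 9.85e-05), NRF2 genes in 21 of 25 (median -0.17, camera adjusted p = 0.00484) and interferon response genes in 17 of 21 (median -0.59, camera adjusted p = 0.0227). With an estimated correlation the adjusted p was 0.580 for the first 3 of these and 0.590 for interferon response. Ifit3, an antiviral gene, fell over the list alone (-1.33 ± 0.35). It was negative for ribosomal proteins (39 of 39, median -0.48, camera adjusted p = 1.22e-07) and oxidative phosphorylation (38 of 38, median -0.32, camera adjusted p = 1.99e-05), where an estimated correlation gave an adjusted p of 0.590 and 0.630. It was positive for glutamatergic synapse (28 of 35, median 0.36, camera adjusted p = 1.64e-04), GABAergic synapse (20 of 22, median 0.28, camera adjusted p = 6.47e-04), calcium handling (30 of 37, median 0.45, camera adjusted p = 5.61e-04) and cerebellar interneuron genes (6 of 7, median 0.36, camera adjusted p = 0.0227). These 4 lists had an adjusted p of 0.580 with an estimated correlation. Xist (9.36 ± 2.15, and 0.33 without the libraries holding both sexes' transcripts, among them sham males 9 and 11), Cacng8, an auxiliary subunit of AMPA receptors (0.86 ± 0.24), and Gpr26, an orphan receptor gene (1.55 ± 0.44), were among the genes of lowest p. edgeR called 0 genes (smallest adjusted p = 0.774) with 254 at an unadjusted p under 0.05, limma called 0, and DESeq2 called 4, among them Xist, Eif2s3y and Ddx3y.

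Several lists were not called in any of the 6 PCB52 comparisons. For targets of the xenobiotic receptors CAR and PXR the lowest camera adjusted p was 0.0541 (female cerebellum, median -0.07), for thyroid hormone-responsive genes 0.397, for interferon response 0.229, for circadian clock 0.0958, for steroid receptors and steroid synthesis 0.352 and for the heat shock and unfolded protein response 0.717. Among cell type lists, the lowest camera adjusted p was 0.791 for striatal interneurons, 0.154 for thalamic, septal or hypothalamic neurons, 0.323 for Purkinje cells, 0.0773 for cerebellar granule cells, 0.120 for Bergmann glia, 0.457 for endothelium, 0.384 for mural cells, 0.285 for ependyma and 0.0773 for blood cells.

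The PCB52 effect differed between regions in the same broad lists. The striatal minus the cerebellar effect, as the mean of both sexes, was negative for ribosomal proteins (median -0.69, camera adjusted p = 6.74e-13) and oxidative phosphorylation (median -0.53, camera adjusted p = 1.60e-10), each with an adjusted p of 0.795 with an estimated correlation. It was positive for glutamatergic synapse (median 0.26, camera adjusted p = 2.14e-04), GABAergic synapse (median 0.19, camera adjusted p = 0.0241), calcium handling (median 0.28, camera adjusted p = 0.0241) and cerebellar granule cell genes (median 1.29, camera adjusted p = 0.0203). These 4 lists also had an adjusted p of 0.795 with an estimated correlation. The granule cell list mean was 5.81 in striatum PCB52 female 22 and at most 4.81 in the other striatal libraries. With the animal as a block the choroid plexus list was called as well (camera adjusted p = 1.99e-04, and 0.0642 without the block). Striatum PCB52 female 20 held 10643 CPM of Ttr, a choroid plexus gene, and cerebellum sham male 1 held 2193 CPM, against at most 82.0 and 25.1 CPM in the other libraries of each region. Single genes of lowest p were Ttr (6.51 ± 1.53, 2.20 with the block, and 0.74 without other tissues' libraries), Gas2l2 (3.63 ± 0.85), Fosb (1.40 ± 0.35), Slc9a3, a sodium-proton exchanger gene (1.42 ± 0.37), Tmem141 (-0.67 ± 0.16) and Luc7l, a splicing gene (0.30 ± 0.08), with an edgeR adjusted p of 0.268. Mean levels were 0.185 CPM for Gas2l2 and 1.37 for Fosb in cerebellum and 0.811 for Slc9a3 in striatum, so these effects rest on few counts in that region. edgeR called 0 genes, DESeq2 called 3 and limma 0. In edgeR 2278 genes had an unadjusted p under 0.05, where independent genes without an effect would give about 622. Of 50 relabellings of the animals, the real one included, 4 gave as many as 2278.

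Male and female log2 fold changes correlated across genes with a Pearson r of 0.0408 and a Spearman rho of 0.0927 in striatum, and 0.214 and 0.417 in cerebellum, where genes are not independent replicates. The sexes share no animals. Of genes at an unadjusted p under 0.05 in both sexes, 4 were higher in both in striatum where independent lists would give 4.13, 5 were lower in both where 3.23 would be given, and 7 were opposite. In cerebellum 27 were higher in both (17.5 for independent lists), 27 were lower in both (9.18), and 4 were opposite. The PCB52 cerebellum groups of both sexes held libraries of high ribosomal level, 4 in all, and the sham groups held none. Genes that vary together with that level could agree between the sexes for this reason, which independent lists do not allow for. Whether the agreement reflects PCB52 was not tested.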

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

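The tests on transcripts of both sexes and of other tissues and the permutation of exposure for ribosomal proteins were chosen after the result was seen; the other tests were planned. Of 203 groups examined for a single library far from the rest, 18 held one, and chance alone gives about 1 in 20 groups.

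The libraries far from the rest of their group were these. Total counts were high in cerebellum sham male 3 (8442982) and cerebellum PCB52 male 21 (10436049). Xist was high in striatum sham male 3 (135 CPM) and Eif2s3y in cerebellum sham female 8 (32.9 CPM). Striatum sham female 12 had high list means for oxidative phosphorylation (8.11), ribosomal proteins (9.34), meningeal fibroblasts (4.27) and the olfactory bulb panel (5.76). Striatum PCB52 female 20 had high means for choroid plexus (7.65) and meningeal fibroblasts (5.46), and cerebellum sham male 1 for choroid plexus (6.04). Cerebellum sham male 3 was high in dopamine signalling (4.33) and cholesterol synthesis genes (5.98), striatum PCB52 male 21 in glucocorticoid-responsive genes (5.19), and striatum sham male 9 was low in GABAergic synapse genes (6.24). The sex chromosome list was high in striatum sham male 3 (6.84) and PCB52 male 19 (6.13) and low in PCB52 female 18 (5.16).

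A difference between sexes in the PCB52 effect was called by camera in striatum for oxidative phosphorylation (adjusted p = 6.39e-08), ribosomal protein (8.26e-10), dopamine signalling (0.0119), glucocorticoid-responsive (3.56e-05), thalamic, septal or hypothalamic neuron (0.0292), choroid plexus (0.00657) and meningeal fibroblast genes (0.0308). In cerebellum it was called for oxidative phosphorylation (1.99e-05), ribosomal protein (1.22e-07), NRF2 (0.00484), calcium handling (5.61e-04), glutamatergic synapse (1.64e-04), GABAergic synapse (6.47e-04), interferon response (0.0227), glucocorticoid-responsive (9.85e-05), cerebellar interneuron (0.0227), oligodendrocyte (1.42e-07) and microglial genes (0.00160). A difference between regions was called for oxidative phosphorylation (1.60e-10), ribosomal protein (6.74e-13), calcium handling (0.0241), glutamatergic synapse (2.14e-04), GABAergic synapse (0.0241) and cerebellar granule cell genes (0.0203). With an estimated correlation none of these 24 was called by camera, with adjusted p-values of 0.712 in striatum, 0.580 to 0.630 in cerebellum and 0.795 between regions.

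Transcripts of both sexes stood together in 5 sham libraries, striatum male 3 and cerebellum 8, 9, 10 and 11. A property of the animal was argued against, since 0 of these animals' libraries of the other region held both. RNA or reads of a male and a female mixed in 1 library may be the source: the male share by Eif2s3y and Ddx3y and the female share by Xist summed to a median of 0.918, near the 1 that mixing needs, with single sums from 0.680 to 1.26. A library of 1 sex also sums to about 1, and Xist ran from 178 to 870 CPM in the other 10 cerebellar females. The sum therefore adds little on mixing beyond the presence of both markers. A swap of whole libraries between the sexes together with such mixing could not be told apart, since 3 of the 5 (cerebellum 8, 9 and 11) held a larger share of the sex that is not on their label, with a female share of 0.594 and a male share of 0.0857 in male 9. At which step mixing took place stays open, and no biological explanation was tested.

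The ribosomal protein list was high in cerebellum PCB52 libraries 15, 16, 20 and 23. Within the 11 sham cerebellar libraries, ribosomal and glutamatergic synapse list means were already opposed (Pearson r = -0.955, permutation p = 1.0e-05, the smallest that the permutations could give), so a preparation or RNA quality axis present without exposure may be part of it. Depth could not be told apart (Spearman rho with the total count 0.311, permutation p = 0.162; Pearson r = -0.0995, permutation p = 0.668, and -0.0205 without the 2 farthest libraries), since 22 libraries leave a wide range around that value. Exposure itself could not be told apart either: list means were 8.93 ± 0.711 in exposed and 8.56 ± 0.356 in sham libraries (SD, n = 11 each), with a permutation p of 0.136 and 4 of 11 above the sham maximum. An effect of PCB52 on these genes therefore stays open beside the axis. Sham animals were numbered 1 to 12 and PCB52 animals 13 to 24. A preparation order that followed the numbers, which is not known, could not be separated from exposure.

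Another tissue's transcripts stood out in 7 libraries: choroid plexus genes in striatum PCB52 female 20 and cerebellum sham male 1, cerebellar granule cell genes in striatum PCB52 female 22, olfactory bulb genes in striatum sham female 12, and genes of the forebrain neuron panel, chosen partly from these libraries, in cerebellum PCB52 females 16, 18 and 24. Of the cortical excitatory list, chosen beforehand, 4 of 27 values in the last 3 exceeded 2 times the cerebellar median (14.8%), and 0 of 9 in female 16. This count cannot decide on cortical tissue, since members such as Slc17a7 were already high in cerebellum (median 1017 CPM, and 25.9 in striatum). A small admixture could not double them. For these 3, mixing with a striatal library was argued against, since the share from Ppp1r1b and Drd1 was a median of -0.0391 of that from Nrgn. The source of these transcripts was not tested otherwise and stays open, and no biological explanation was tested. The count of 7 libraries holds for the lists checked. In striatum the cortical and thalamic lists were not among them, though Slc17a7 reached 371 CPM there against a median of 25.9.

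When libraries were relabelled at random, fewer than 5 in 100 splits matched the real count only for the sexes in striatum. There 1 of 100 splits in sham animals and 3 of 100 in PCB52 animals called as many genes as the real 4 and 5, the real one included, with a highest other of 1 and 75. With 75 in another split and no adjustment over these tests, the split count does not exclude chance in PCB52 animals. The other comparisons had 0 genes past the adjusted threshold and were judged by unadjusted p, a different measure. At an unadjusted p under 0.05, chance could not be excluded for PCB52 in striatum in males (109 genes, highest other 1789, 84 of 100 splits as large), females (1633, 4522, 25), the mean of both (704, 3522, 30) or the interaction (471, 4299, 30). Nor could it in cerebellum in males (1673, 6164, 16), females (369, 4173, 19), the mean of both (1727, 5609, 8), the interaction (254, 7018, 35), or between the sexes in sham (123, 2529, 60) and PCB52 animals (379, 7803, 44). In the region comparison 4 of 50 splits were as large (2278, highest other 6524). Some other splits reached several times the real counts, which points to a structure of the samples beyond the groups. The median split lay below the real count except in striatum males (153) and between the sexes in sham cerebellum (140), and was 202 for the cerebellar mean. Some features of libraries did follow exposure. The 4 cerebellar libraries of high ribosomal level were all PCB52, and the 5 libraries with both sexes' transcripts were all sham.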

How the results depend on the processing

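The settings that leave out libraries with both sexes' transcripts, another tissue's transcripts or a high ribosomal level, and the ribosomal covariate, were chosen after the result was seen. Counts of genes past the threshold are given first. In edgeR they were 0 in each PCB52 comparison, and 0 with RLE size factors, without a filter on low counts and without any 1 library, for PCB52 in either region and sex, the mean of both, the interactions and the region comparison. With the replicate block by animal the region comparison also gave 0, and its count at an unadjusted p under 0.05 was 1881 against 2278; no other comparison holds an animal more than once. DESeq2 gave 1 in striatum males, 23 in striatum females, 1 in cerebellum males, 9 in cerebellum females, 21 for the cerebellar mean, 4 for the cerebellar interaction, 9 between the sexes in PCB52 cerebellum and 3 between regions. limma gave 2 between the sexes in PCB52 cerebellum. Surrogate variables gave 5 in cerebellum females, 60 for the cerebellar mean and 1 between the sexes in PCB52 cerebellum. With only the libraries compared, the sexes gave 2 in sham striatum and 4 in PCB52 cerebellum. Without libraries holding both sexes' transcripts they gave 4 in sham and 5 in PCB52 cerebellum, and with the ribosomal covariate 1 in PCB52 cerebellum. Leaving out 1 library gave 3 to 5 in sham striatum, 5 in PCB52 striatum, 0 to 2 in sham cerebellum (2 without sham female 8) and 0 in PCB52 cerebellum. Counts of lists called by camera in the order males, females, mean, interaction, sexes in sham, sexes in PCB52 were 1, 8, 6, 7, 7 and 9 in striatum and 6, 12, 7, 11, 10 and 8 in cerebellum. They were 0 with an estimated correlation except for 1 in cerebellum females. fry called 0 except for 1, the sex chromosome list, between the sexes in sham and in PCB52 striatum. Without libraries holding both sexes' transcripts the count was 0 in striatum males and 16 for the sexes in sham cerebellum. Without those holding another tissue's it was 2 in striatum males, 11 for the striatal interaction and 4 for the sexes in sham cerebellum. Without those of high ribosomal level it was 0 in striatum males, 13 in striatum females and 4 for the sexes in sham striatum, and with the ribosomal covariate 3 in striatum males, 12 for the striatal and 6 for the cerebellar interaction. Leaving out 1 library gave 0 to 10 lists in striatum males (10 without sham male 9), 6 to 13 in females (13 without sham female 12), 4 to 11 for the mean (11 without PCB52 female 20), 4 to 10, 4 to 11 and 9 to 13, and in cerebellum 5 to 9, 5 to 12 (5 without PCB52 female 14), 5 to 10, 9 to 13, 4 to 15 and 4 to 10. Causes of these changes were not tested.

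Some directions turned. Values of genes are log2 fold changes and those of lists are camera adjusted p-values with the direction opposite to the one in the report. In striatum, Th in females was 7.09e-04 with limma, 0.59 without other tissues' libraries and 0.33 without the high ribosomal libraries or sham female 12 (from -2.60 over left-out libraries); Xist in males was 0.052 without sham male 3 (-5.98 to 0.052 over left-out libraries), the only striatal library with both sexes' transcripts; and Ttr in females was -0.12 without other tissues' libraries. For the sexes in sham striatum, oxidative phosphorylation was at 0.717 without other tissues' libraries and 0.679 without sham female 12 (also the high ribosomal setting), and ribosomal proteins at 0.411 and 0.340. Over left-out libraries these ran from 3.40e-07 to 0.679 and from 4.04e-06 to 0.362. For the sexes in PCB52 striatum, choroid plexus was at 0.997 without other tissues' libraries and 0.991 without PCB52 female 20 (from 3.905e-04 over left-out libraries). With the ribosomal covariate, glutamatergic synapse in striatum females was at 0.606 and oxidative phosphorylation at 0.833 for the interaction and 0.373 for the sexes in PCB52 striatum. In cerebellum females without libraries holding both sexes' transcripts, Col1a1 was 0.053, and Ddx3y had 0 counts in every female library left and so no direction; without other tissues' libraries, Ddn was -0.87, Camkv -0.21, Nrgn -1.06 and Socs3 -0.16. Ttr for the sexes in sham cerebellum was 0.28 without other tissues' libraries and 0.29 without sham male 1 (from -6.00 over left-out libraries). The high ribosomal setting left out 4 cerebellar libraries, all PCB52, by the level of the ribosomal list, so a fall of that list and of genes that follow it was fixed by the choice and shows no reversal. With it, cerebellum females had Ndufb8 at -0.19, Rplp2 at -0.19, Rpl35 at -0.23, oxidative phosphorylation at 2.82e-07 and ribosomal proteins at 2.90e-08. The cerebellar mean had Ndufb3 at -0.035, Rpl32 at -0.033, oxidative phosphorylation at 0.0195, ribosomal proteins and calcium handling at 0.114 each and glutamatergic synapse at 0.419. With the ribosomal covariate, oxidative phosphorylation was at 3.91e-04 in cerebellum males, 0.989 in females, 0.0451 for the mean, 0.00253 for the interaction and 0.00141 for the sexes in PCB52 cerebellum. Calcium handling was at 0.974 in males, 0.497 for the mean and 0.651 for the sexes, and glutamatergic synapse at 0.690 for the mean and 0.765 for the sexes. In cerebellum females oxidative phosphorylation was at 0.671 without PCB52 female 16 and 0.490 without PCB52 female 20, and ribosomal proteins at 0.492 without PCB52 female 20. Over left-out libraries, in either direction, these ran from 2.25e-04 to 0.693 and from 7.88e-06 to 0.898. Leaving out a library chosen for its high transcripts shows which library carried a value and not the cause, which was not tested. The covariate is likewise made from the ribosomal list. The glucocorticoid-responsive list in cerebellum females kept its direction and call in each camera alternative, from 1.45e-14 to 0.0425, and had 0.106 by fry. Only the 0.0425 came from an estimated correlation, and the other settings of camera kept the preset one. Depth of 5684508 to 15865054 counts limits genes near 1 CPM.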

Other observations

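The tests on the glucocorticoid-responsive list by animal were chosen after the result was seen.

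The mean of the glucocorticoid-responsive list varied together in striatum and cerebellum of the same animals. Over 21 animals with both regions, the deviation of an animal's list mean from its group correlated between regions with a Pearson r of 0.756 (permutation p = 4.5e-04, adjusted over 33 lists 0.0149) and a Spearman rho of 0.617 (permutation p = 0.00588, adjusted 0.0647). Without the 2 farthest animals r was 0.614, and it was 0.561 within 10 sham and 0.911 within 11 PCB52 animals. A state of the animal shared by both regions, such as its corticosterone level at death, may therefore set this list. Library quality shared by an animal's libraries could not be told apart: the ribosomal list had an r of 0.0620 over all animals, but 0.590 within sham and -0.245 within PCB52 animals. Corticosterone was not measured in the data used here, so whether PCB52, handling or time of death set the level stays open. Interferon response genes had the next lowest p, with an r of 0.580 (permutation p = 0.00346, adjusted 0.0571), and a rho of 0.687 (permutation p = 0.00103, adjusted 0.0340).

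With the animal as the unit, an exact permutation of the glucocorticoid list mean gave 4.34 ± 0.227 in PCB52 and 4.77 ± 0.223 in sham female cerebellum (SD, n = 6 each), p = 0.00866 and 0.0346 adjusted over the 4 tests, with 6 of 6 PCB52 libraries below the sham mean. The list was singled out by its camera result in these same libraries. Adjustment over 4 tests does not cover that choice among lists, so this p is not independent support. In female striatum the means were 4.69 ± 0.300 and 5.03 ± 0.221 (SD, n = 6 each; exact p = 0.0519, adjusted 0.104), with 5 of 6 below the sham mean. In males the differences were 0.042 in striatum (exact p = 0.838) and -0.018 in cerebellum (exact p = 0.913). Libraries with transcripts of both sexes were then left out. In cerebellum the difference was 0.12 in males (5 PCB52 and 3 sham, exact p = 0.321) and -0.48 in females (6 and 4, exact p = 0.0190, 0.0762 adjusted over the 4 tests). The female call by animal was thus lost after adjustment with 2 sham libraries fewer.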
